A study of Mus musculus with 18 samples.

How the data were processed

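RNA sequencing libraries of primary mouse bone-marrow-derived macrophages were analysed: 18 libraries in 6 groups of 3. The groups, taken from the sample labels, were a control, interferon-gamma (IFNg), and IFNg combined with tumour necrosis factor (TNF), interleukin-1 beta (IL1b), lipopolysaccharide (LPS) or hypoxia, all at 18 h. Per the labels' protocols, libraries were made from 100 ng of total RNA with a stranded poly(A) kit and sequenced as single-end reads of 50 bp. The number in each sample's title was taken as its replicate number. The labels do not state that the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

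Each deposited file gave the authors' read count per gene, the gene's width and an RPKM value, which scales reads to gene width and library total, for 22598 genes. Reads were aligned with GSNAP to the mm10 build, per the submitters' processing notes. The counter, its annotation, its use of strand and the versions are not given in the sources used here, so overlapping genes and near-identical copies could share reads. This applies to the guanylate-binding protein (Gbp), Ifit and MHC class I (H2-Q) families, the neighbouring Clec4n, Clec4d and Clec4e, and mt-Nd5 and mt-Nd6, which overlap on opposite strands. Of the deposited widths, 86.7% were multiples of 3. Among 22355 genes with a coding length in GENCODE M21, 91.2% had a width within 5% of the union of their coding exons. The deposited counts were therefore treated as counts over coding parts, which leaves out reads in untranslated regions. All rows named a gene, and 22457 gene identifiers were matched to a symbol through GENCODE M21, while 141 had none and 8 rows shared a symbol with another row. Gene positions are mm10 coordinates of that annotation.

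Total counts ran from 12270565 to 20952799 per library. The RPKM values deposited by the authors implied library totals of 22728833 to 39859629 reads, of which 51.68 to 56.45% were counted in genes. RPKM values were used only for those totals. Levels are given as CPM, a gene's count divided by the library's count in tested genes times its TMM factor, as mean ± SD of 3 libraries. A floor of 3 counts in a library stood at 0.151 to 0.255 CPM on that scale. Against a group with 0 counts in all its libraries, the fold was bounded with 3 counts over the group, and a group with 1 to 3 counts was given as a ratio with its 95% counting interval. Intervals and floors cover counting error only, since counts of 5 to 50 varied between replicates with a variance 6.2 to 10.7 times their mean.

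Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, R 4.3.3), with TMM normalization and the default filterByExpr, in 1 model with a mean per group over all 18 libraries. After the filter, 11563 genes were tested. Every adjusted p of a gene is edgeR's after Benjamini-Hochberg adjustment within its comparison, with 0.05 as the threshold, and each log2 fold change is followed by its standard error (SE), computed from the fold change and the test's F. TMM factors ran from 0.805 to 1.186. The 7 comparisons were IFNg against control, each of the 4 additions against IFNg, LPS against TNF, and TNF against IL1b. Because no addition was made without IFNg, the effect of an addition cannot be separated from its combination with IFNg.

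In all, 22 pathway lists and 11 lists of cell type markers were fixed before the data were examined, together with the groups, the tests, most of the alternative settings and the rule for named genes. The pathway lists were the IFNg response, MHC class II, MHC class I processing, the type I interferon response, inflammatory cytokines, chemokines, the NF-kappaB pathway and its targets, nitric oxide and antimicrobial effectors, the hypoxia response, glycolysis, the tricarboxylic acid (TCA) cycle, oxidative phosphorylation, cholesterol biosynthesis, cholesterol efflux and lipid handling, the cell cycle, alternative activation and resident macrophage genes, immune checkpoint and costimulation, inflammasome and cell death, receptors and adaptors of the stimuli, the unfolded protein and integrated stress response, the lysosome, and oxidative stress and heme. The marker lists were macrophage identity, T cell, B cell, NK cell, neutrophil and granulocyte precursor, mast cell and basophil, dendritic cell, fibroblast and stroma, endothelial, erythroid and megakaryocyte. Of the pathway list genes, 4 were not matched and were not used here. Pathway lists were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera called 94 of 154 list results. With an estimated correlation 65 calls held, 29 were lost and 0 were gained, and a lost call is given with that p beside it. Counts of list members are given over all genes tested and adjusted over the list alone. Of the lists in the 7 comparisons, 41 held a gene at 0 counts in 1 group, and in 2 of these the median differed with such genes at their bounds. Members at or under 3 counts in both groups were given no change in such a median.

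The named genes of a comparison were the 6 largest higher and the 6 largest lower (4 each for the comparisons between additions) among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the 3 libraries of each group, passing over predicted names. Added to these were the 3 largest changed members of each called list and 15 fixed genes, of which these 14 are reported: Ciita, H2-Ab1, Cxcl9, Cxcl10, Nos2, Il1b, Il6, Il12b, Tnf, Cd274, Arg1, Ifit1, Vegfa and Slc2a1. Receptors, cell type markers, mitochondrially encoded genes and the few members named because they moved against or with their list were taken from the lists after their values were seen. Some single genes under this rule are not reported here, although they stayed in the tests and in the counts of genes and of list members.

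Comparisons that share the IFNg libraries share their chance values. Overlaps were therefore set beside simulated unchanged groups (20 draws) and beside the overlap of independent lists of the same sizes. The 3 IFNg libraries cannot be split into parts of at least 2, so part of an excess may come from the shared controls. The alternatives were DESeq2's size factors, no filter on low counts, DESeq2 1.42.0 in place of edgeR, only the 6 libraries compared, the replicate number as a block, a 2-fold threshold, each library left out in turn, an estimated correlation in camera, and fry, which tests whether a list moves one way and does not compare it with other genes. Added after seeing the data were scaling to the RPKM totals in place of TMM, and leaving out the third libraries of IFNg with TNF and IFNg with LPS. The steps were tested on simulated counts drawn from the real means and depths, with 200 genes changed per comparison and 0 calls of the wrong sign. Among unchanged genes 1 was called for IFNg against control, 5 for TNF, 5 for IL1b, 3 for LPS and 8 for hypoxia, and camera called 1 list for TNF, where none had been planted, and 0 for the others. At 2-fold, 46.3% of changed genes were recovered for IFNg against control, 61.2% for TNF, 59.7% for IL1b, 55.2% for LPS and 44.8% for hypoxia against IFNg. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.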

Results

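Gene expression was measured by RNA sequencing in mouse bone-marrow-derived macrophages, which are macrophages grown in culture from bone marrow cells. After 18 h, 3 libraries were made from each of 6 groups: a control, cells given interferon-gamma (IFNg, the cytokine that activates macrophages against intracellular microbes), and cells given IFNg with tumour necrosis factor (TNF), with interleukin-1 beta (IL1b), with lipopolysaccharide (LPS, a bacterial cell wall component sensed through Tlr4) or with hypoxia. The 18 libraries held 12270565 to 20952799 counts each, the fewest in the third IFNg and IL1b library and the most in the first IFNg and TNF library. No library was a copy of another of its group, since the chi-square per degree of freedom between replicates was 11.9 to 50.6. The first principal component of the tested genes held 38.4% of the variance. It placed the control libraries at -93.9 to -90.7, IFNg at -37.3 to -33.5, IL1b at -28.4 to -21, hypoxia at 15.5 to 18.9, LPS at 33.2 to 36.8 and TNF at 92.7 to 112.3. Below, an addition is named alone, but IFNg was present in each.

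Scaling the libraries to the totals behind the authors' RPKM values in place of TMM, chosen after seeing the data, moved the median log2 fold change of all genes by -0.152 for IFNg against control. The shift was -0.319 for TNF, 0.006 for IL1b, -0.076 for LPS and -0.245 for hypoxia against IFNg. It was 0.243 for LPS against TNF and -0.325 for TNF against IL1b. Directions below are those under TMM. Where the RPKM totals moved the share of higher calls in a list or comparison given below by over 10 percentage points, or the number of calls by over 1.5 times, the split under them stands in the same paragraph. DESeq2's size factors moved 0 of the list counts that far.

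**Figure D1:**
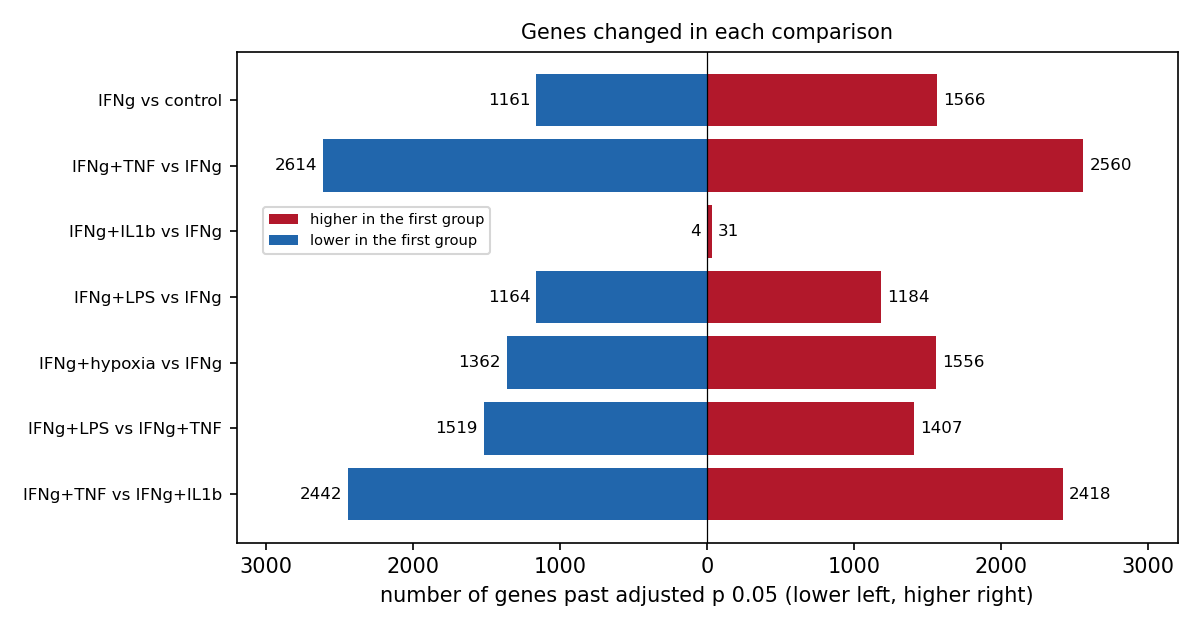
Number of genes past an adjusted p of 0.05 (edgeR) in the 7 comparisons, with genes higher in the first group as red bars to the right and genes lower as blue bars to the left. The bars run from 35 genes for IL1b to 5174 genes for TNF, each against IFNg.

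IFNg against control asked what IFNg alone changed. Gbp2b (ENSMUSG00000040264, chromosome 3, 142594847 to 142619179), a guanylate-binding protein gene, went from 0 counts in control to 1941 ± 37.3 CPM (SD, n = 3), at least 34100-fold higher (adjusted p = 1.27e-20). The protease inhibitor gene Serpina3f (ENSMUSG00000066363, chromosome 12, 104214544 to 104221129) had 0 counts in control and 307 ± 35.0 CPM with IFNg, at least 5380-fold higher. Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), the master regulator of MHC class II genes, rose from 38.9 ± 10.3 to 749.5 ± 45.0 CPM, a log2 fold change of 4.27 ± 0.15 (adjusted p = 2.89e-18). Cx3cr1, the fractalkine receptor, fell from 190.8 ± 31.5 to 5.46 ± 2.74 CPM (adjusted p = 1.59e-05), and S1pr1, a receptor for sphingosine-1-phosphate, fell from 89.3 ± 11.5 to 2.33 ± 1.13 CPM (adjusted p = 2.89e-13).

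All 29 measured genes of the IFNg response list rose (29 adjusted over the list alone), with a median of 5.11 (camera adjusted p = 1.19e-227). The chemokine gene Cxcl9 rose by 11.68 ± 0.36 on the log2 scale, to 521 ± 22.6 CPM from 0.135 ± 0.233. Cxcl10 rose by 4.09 ± 0.24. Of 12 MHC class II genes, 11 rose (11 adjusted over the list alone; median 3.87, camera adjusted p = 1.4e-42), among them H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), which rose from 92.9 ± 20.3 to 1380 ± 181 CPM. All 22 genes of MHC class I processing rose (22 adjusted over the list alone; median 1.59, camera adjusted p = 2.29e-31), with Tapbpl, a peptide-loading editor, up by 3.11 ± 0.15. In the type I interferon list 28 of 36 rose (29 adjusted over the list alone; median 0.84, camera adjusted p = 2.5e-15), with Ifi44 up by 3.28 ± 0.13 and Ifit1 by 0.90 ± 0.14. Checkpoint and costimulation genes counted 9 higher and 2 lower of 21 (9 and 2 adjusted over the list alone; camera adjusted p = 7.78e-06). Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which encodes PD-L1, rose from 15.1 ± 3.48 to 296 ± 22.8 CPM (adjusted p = 2.05e-18), and Pdcd1lg2, which encodes PD-L2, was at least 48.4-fold higher.

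Of 25 genes of nitric oxide and antimicrobial effectors, 9 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 4.79e-05). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose from 0.601 ± 0.173 to 24.9 ± 7.71 CPM (adjusted p = 2.52e-10). Arg1, which breaks down arginine, had 0 counts in control and was at least 73.7-fold higher at 4.23 ± 0.440 CPM. Inflammasome and cell death genes counted 16 higher and 2 lower of 34 (16 and 2 adjusted over the list alone; camera adjusted p = 0.00037), with Zbp1, a nucleic acid sensor, up by 2.70 ± 0.11. Genes of the unfolded protein and integrated stress response counted 15 higher and 1 lower of 25 (15 and 2 adjusted over the list alone; camera adjusted p = 2.95e-05), with the endoplasmic reticulum factor Manf up by 1.75 ± 0.16. Glycolysis genes counted 11 higher and 1 lower of 19 (12 and 1 adjusted over the list alone; camera adjusted p = 2.95e-05, adjusted p = 0.0637 with an estimated correlation), with Hk3 up by 2.94 ± 0.16 and the glucose transporter gene Slc2a1 by 1.62 ± 0.15. In cholesterol biosynthesis 14 of 22 genes fell and 0 rose (14 adjusted over the list alone; median -1.24, camera adjusted p = 4.8e-06). Sqle, the squalene epoxidase, fell by 2.60 on the log2 scale with an SE of 0.29. In the oxidative stress and heme list 18 of 24 fell and 1 rose (20 and 1 adjusted over the list alone; median -0.78, camera adjusted p = 4.8e-06, adjusted p = 0.0958 with an estimated correlation), with Nqo1 at -2.58 ± 0.63 and the iron exporter gene Slc40a1 at -2.46 ± 0.22.

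No list call was made for the remaining lists, each given with its members higher and lower and, in brackets, the same counts adjusted over the list alone. These were inflammatory cytokines with 6 and 1 (6 and 3), NF-kappaB with 6 and 4 (6 and 4), hypoxia with 3 and 8 (4 and 8), TCA cycle with 9 and 2 (11 and 2), oxidative phosphorylation with 14 and 0 (15 and 0), lipid handling with 6 and 9 (7 and 11), cell cycle with 5 and 11 (6 and 14), alternative activation with 9 and 13 (9 and 14) and lysosome with 4 and 11 (5 and 12). Chemokines had 5 and 3 (5 and 3), with a median of -0.17, a mean of 0.88 and an upward test (camera adjusted p = 0.206). Receptors of the stimuli had 11 and 4 (12 and 7), with a median of 0.17, a mean of -0.14 and an upward test (camera adjusted p = 0.355). With RPKM totals cytokines had 5 and 3, the TCA cycle 6 and 3 and the cell cycle 3 and 14. Tnf rose from 3.24 to 26.4 CPM by 3.04 ± 0.24. Il1b (0.03 ± 0.52, adjusted p = 0.986) and Vegfa (0.44 ± 0.22, adjusted p = 0.167) did not pass the test, and Il6 and Il12b had 0 counts in both groups. Among macrophage identity markers 2 rose and 8 fell of 12, and in the granulocyte list 1 of 10, Mmp8, fell. Klrk1, the only measured NK cell marker, rose to 85.1 CPM (7.14 ± 0.52, adjusted p = 5.96e-09), and of 5 T cell markers Il7r fell from 127.4 to 51.3 CPM (adjusted p = 3.55e-05). Of 11563 genes tested, 2727 changed (1566 higher and 1161 lower, or 23.6%), 1292 of them at least 2-fold. With RPKM totals 3003 changed, 1207 higher and 1796 lower.

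**Figure D2:**
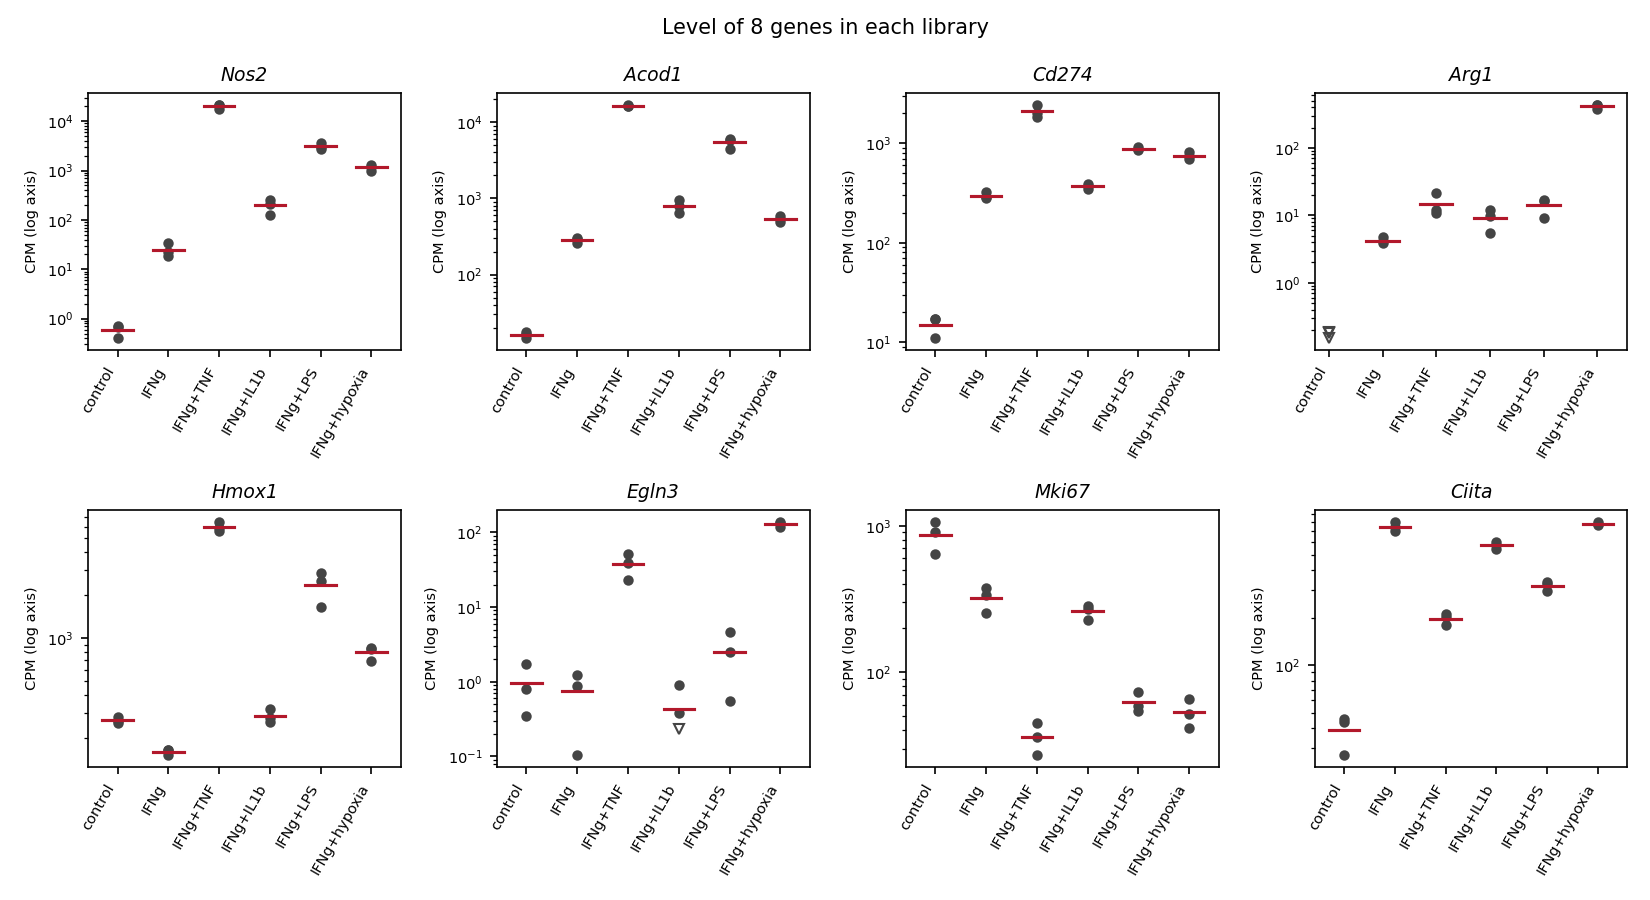
Levels in CPM (log axis) of 8 genes in the 6 groups, with dots for the 3 libraries of a group, a red line at their mean and an open triangle at a library's floor of 3 counts where it had 0 counts. Nos2 stood at 24.9 CPM with IFNg and at 20100 CPM with added TNF.

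TNF added to IFNg changed more genes than any other comparison made here. Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), the cystine transporter, had 1 count in the 3 IFNg libraries and 303 ± 37.1 CPM with TNF, a ratio of 15400 (95% counting interval 2750 to 606000). Nos2 rose from 24.9 ± 7.71 to 20100 ± 1774 CPM, a log2 fold change of 9.66 ± 0.30 (adjusted p = 2.48e-15, n = 3). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), which encodes the inflammatory cytokine, rose from 2.25 ± 0.773 to 1688 ± 160 CPM (adjusted p = 9.84e-11). Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), the heme oxygenase, rose from 160 ± 6.93 to 5970 ± 446 CPM by 5.22 ± 0.17. Abca9 (ENSMUSG00000041797, chromosome 11, 110100749 to 110168196), a membrane transporter gene, went from 20.5 ± 3.34 CPM to 0 counts, at least 310-fold lower.

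NF-kappaB genes counted 30 higher and 1 lower of 35 (31 and 1 adjusted over the list alone), with a median of 2.07 (camera adjusted p = 6.09e-28). Ier3 rose by 6.24 ± 0.42 and the inhibitor gene Nfkbie by 4.77 ± 0.30, while Map3k8 fell. Inflammatory cytokines counted 14 higher and 3 lower of 21 (14 and 3 adjusted over the list alone; median 2.59, camera adjusted p = 0.000537). Il6 was at least 304-fold higher at 17.6 ± 5.19 CPM and Il12b at least 123-fold higher at 7.24 ± 2.56 CPM, both from 0 counts, and Tnf itself rose by 2.59 ± 0.22. Il10, Il16 and Tnfsf10 fell, and with RPKM totals the list had 13 higher and 5 lower. Chemokines split, with 7 higher and 5 lower of 17 (7 and 6 adjusted over the list alone), a median of -0.08, a mean of 0.92 and an upward test (camera adjusted p = 0.0697, but a call with RPKM totals at 0.0266). Cxcl2 rose by 8 ± 0.66 and Cxcl3 was at least 262-fold higher, while Ccl3, Ccl4, Ccl6 and Ccl9 fell. In the nitric oxide and antimicrobial effector list 16 rose and 5 fell of 25 (18 and 5 adjusted over the list alone; camera adjusted p = 1.6e-10), with Arg2 at least 879-fold higher and the prostaglandin E synthase gene Ptges up by 8.80 ± 0.82. Arg1, outside that list, rose by 1.81 ± 0.30.

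Hypoxia response genes rose with TNF as well, 26 higher and 3 lower of 34 (29 and 3 adjusted over the list alone; median 2.64, camera adjusted p = 2.79e-16). Vegfa rose from 12.7 to 213 CPM by 4.06 ± 0.23 and Adm was at least 106-fold higher. Glycolysis genes counted 12 higher and 2 lower of 19 (12 and 2 adjusted over the list alone; median 1.34, camera adjusted p = 8.86e-11), with Slc2a1 up from 71.4 ± 1.96 to 1142 ± 49.2 CPM. Oxidative stress genes counted 21 higher and 1 lower of 24 (22 and 2 adjusted over the list alone; median 2.91, camera adjusted p = 4.1e-31), the lower one being Gpx1. In the TCA cycle 12 fell and 1 rose of 24 (12 and 1 adjusted over the list alone; camera adjusted p = 0.0117), with Idh2 at -2.30 ± 0.21 and Pcx, which feeds the cycle from pyruvate, at 2.74 ± 0.29. In oxidative phosphorylation 16 of 51 fell and 0 rose (15 adjusted over the list alone; median -0.35, camera adjusted p = 0.0289, adjusted p = 0.499 with an estimated correlation), and without the second TNF library the camera adjusted p was 0.133. With RPKM totals 33 fell.

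Cell cycle genes fell together, 31 lower and 0 higher of 34 (32 adjusted over the list alone), with a median of -3.08 (camera adjusted p = 8.49e-26). Birc5, a regulator of chromosome segregation, fell from 24.1 to 0.384 CPM, and Plk1 was at -5.04 ± 0.32. Neutrophil and granulocyte precursor markers moved with them, 9 lower and 0 higher of 10, with S100a9 at 42.8 CPM with IFNg and 5.87 CPM with TNF, and Elane at 3.48 CPM and 0 counts. Ltf, a granule protein, fell by 6.22 on the log2 scale with an SE of 0.47. Both measured B cell markers fell, with Ighm at 534 CPM and 9.31 CPM, although Ms4a1 and Pax5 had 0 counts. The NK cell list had 1 measured gene, Klrk1, which fell from 85.1 to 19.9 CPM. Among 5 measured T cell markers Cd247 and Il7r rose, or 1 of them with RPKM totals, with Cd3e, Cd3d and Cd3g at 0 CPM in every group. Macrophage identity markers counted 4 higher and 5 lower of 12, or 3 and 6 with RPKM totals, with Csf1r at 4676 and 7756 CPM and Adgre1 at 2741 and 1648 CPM in IFNg and TNF.

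In the IFNg response list 18 rose and 3 fell of 29 (20 and 3 adjusted over the list alone; median 0.53, camera adjusted p = 2.58e-05), and with RPKM totals 13 rose and 7 fell. Cxcl9 rose by 3.15 ± 0.20 and Cxcl10 by 3.03 ± 0.22, while Gbp2b, Gbp8 and Gbp9 fell, Gbp2b from 1941 ± 37.3 to 111 ± 18.2 CPM. Type I interferon genes counted 27 higher and 2 lower of 36 (27 and 2 adjusted over the list alone; median 0.61, camera adjusted p = 5.37e-07), 16 and 4 with RPKM totals. Oasl1 rose by 3.58 ± 0.17 and Ifit1 by 1.38 ± 0.14. In MHC class II 3 of 12 fell and 0 rose (3 adjusted over the list alone; camera adjusted p = 0.0985), or 7 and 0 with RPKM totals, with Ciita falling from 749.5 ± 45.0 to 196.8 ± 16.5 CPM by 1.93 on the log2 scale (adjusted p = 4.96e-12). H2-Ab1 (0.24 ± 0.14, adjusted p = 0.16) did not pass the test and was at -0.079 with RPKM totals. MHC class I processing had 9 higher and 2 lower of 22 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0862), but 5 higher and 8 lower with RPKM totals.

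Alternative activation and resident genes counted 13 lower and 7 higher of 28 (13 and 7 adjusted over the list alone; median -1.23, camera adjusted p = 0.00388), with the mannose receptor gene Mrc1 at -5.62 ± 0.39. Checkpoint genes counted 11 higher and 3 lower of 21 (11 and 3 adjusted over the list alone; camera adjusted p = 0.00422), or 10 and 5 with RPKM totals, with Cd274 at 2079 CPM, up by 2.81 ± 0.14. The inflammasome list had 13 higher and 4 lower of 34 (13 and 4 adjusted over the list alone; median 0.26, camera adjusted p = 0.023). Receptors of the stimuli had 14 higher and 7 lower of 32 (15 and 7 adjusted over the list alone; median 0.26, camera adjusted p = 0.00874, adjusted p = 0.16 with an estimated correlation), with the LPS co-receptor gene Cd14 up from 148 ± 4.89 to 5321 ± 482 CPM. Both medians were -0.06 with RPKM totals, where the inflammasome list had 9 higher and 8 lower. The other lists were not called: lipid handling with 13 higher and 7 lower (13 and 7 adjusted over the list alone), the stress response with 8 and 10 (8 and 11; median 0.03, or -0.29 with RPKM totals), the lysosome with 8 and 11 (8 and 12), and cholesterol biosynthesis with 5 and 7 (5 and 7), whose median was -0.13 and mean -0.12 under an upward test (camera adjusted p = 0.933). With RPKM totals lipid handling had 9 and 8, the lysosome 5 and 16 and cholesterol biosynthesis 4 and 9. In all 5174 genes changed (2560 higher and 2614 lower, or 44.7%), 2843 of them at least 2-fold. With RPKM totals 5670 changed, 1685 higher and 3985 lower.

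**Figure D3:**
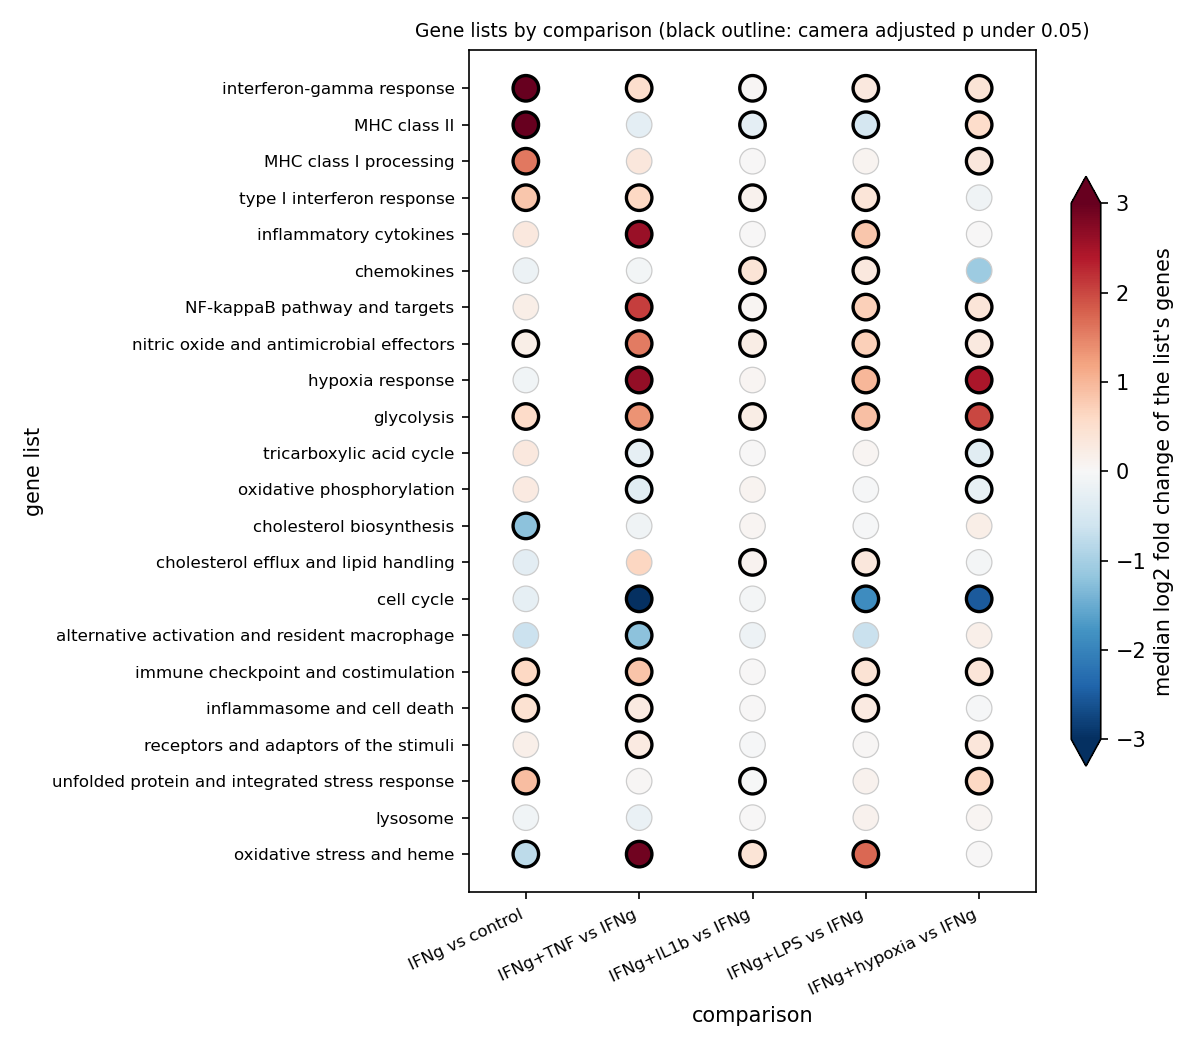
Median log2 fold change of the 22 pathway lists for IFNg against control and for the 4 additions against IFNg, as a colour scale limited to -3 to 3, with a black outline where camera's adjusted p was under 0.05. Cell cycle medians were -3.08 with TNF, -1.88 with LPS and -2.51 with hypoxia, each against IFNg.

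IL1b added to IFNg changed few genes. Nos2 rose from 24.9 ± 7.71 to 198 ± 62.2 CPM (2.99 ± 0.23, adjusted p = 3.42e-07, n = 3). Acod1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573), which makes itaconate, rose from 284 ± 21.3 to 799 ± 162 CPM by 1.49 ± 0.14. The lectin receptor genes Clec4d (ENSMUSG00000030144, chromosome 6, 123262111 to 123275265) and Clec4e rose by 1.90 ± 0.14 and 1.58 ± 0.22, and Fpr2 (ENSMUSG00000052270, chromosome 17, 17887824 to 17893952), a formyl peptide receptor, by 2.25 ± 0.31. Ptgs2, the inducible cyclooxygenase, rose by 1.30 ± 0.16. Of 11563 genes 35 changed (31 higher and 4 lower, or 0.3%) and 596 had an unadjusted p under 0.05, while DESeq2 called 86 (67 higher and 19 lower, 33 shared). Without IFNg library 1 or IL1b library 3, edgeR called 15, without IFNg library 2 it called 21 and without IL1b library 2 it called 23. A model of only the 6 libraries called 68.

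The 4 lower genes were Ramp1 (-1.98 ± 0.41, adjusted p = 0.0272), Pde3b (-1.27 ± 0.25, adjusted p = 0.012), Thbs1 (-0.70 ± 0.14, adjusted p = 0.0187) and Naaa (-0.51 ± 0.11, adjusted p = 0.0227). Ramp1 lost its call without IFNg library 1 (0.214), 2 (0.076) or 3 (0.0582) or IL1b library 2 (0.265) or 3 (0.245), and Pde3b without IFNg library 1 (0.0853) or IL1b library 2 (0.145). Thbs1 lost it without IFNg library 2 (0.148) or 3 (0.0823) or IL1b library 1 (0.0934) or 3 (0.173), and Naaa without IFNg library 1 (0.146) or 3 (0.169) or IL1b library 2 (0.145) or 3 (0.327). In the oxidative stress list 3 of 24 rose and 0 fell (11 adjusted over the list alone; median 0.41, or 0.35 with genes near 0 counts set to no change; camera adjusted p = 3.5e-14). Prdx1, a peroxiredoxin, rose from 294 ± 38.7 to 555 ± 7.33 CPM and Hmox1 from 160 to 285 CPM. In the nitric oxide and antimicrobial effector list 3 of 25 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 1.72e-12).

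Other list calls with IL1b were lost with an estimated correlation. These were the IFNg response with 1 higher of 29 (5 adjusted over the list alone; camera adjusted p = 0.0162, adjusted p = 0.0686 with an estimated correlation), the type I response with 0 of 36 (0 adjusted over the list alone; median 0.14, camera adjusted p = 1.19e-05, adjusted p = 0.0686 with an estimated correlation), and MHC class II with 0 of 12 (0 adjusted over the list alone; median -0.29, camera adjusted p = 4.08e-06, adjusted p = 0.0686 with an estimated correlation). NF-kappaB had 1 higher of 35 (2 adjusted over the list alone; camera adjusted p = 1.19e-05, adjusted p = 0.0686 with an estimated correlation) and chemokines 1 of 17 (1 adjusted over the list alone; median 0.42, or 0.30 with genes near 0 counts set to no change; camera adjusted p = 0.0042, adjusted p = 0.0686 with an estimated correlation). Glycolysis had 0 of 19 (1 adjusted over the list alone; camera adjusted p = 0.000555, adjusted p = 0.119 with an estimated correlation). Lipid handling had 3 of 24 (4 adjusted over the list alone; camera adjusted p = 0.00275, adjusted p = 0.0934 with an estimated correlation), with the scavenger receptor gene Cd36 up by 0.66 ± 0.11. The stress response had 2 of 25 (3 adjusted over the list alone), with a median of -0.01, a mean of 0.20 and an upward test (camera adjusted p = 0.0453, adjusted p = 0.0686 with an estimated correlation). Leaving out IFNg library 2 gave 0.0813 for the IFNg response, and leaving out IFNg library 3 gave 0.0687 for chemokines. For the stress response the value was 0.0773, 0.139, 0.0572 and 0.0964 without IFNg library 1 or 3 or IL1b library 1 or 2. Higher genes also lost their calls when 1 library was left out. Without IL1b library 3 the 1 gene called in the IFNg response (Ubd, adjusted p = 0.0917), NF-kappaB (Sod2, 0.0917) and chemokines (Ccl5, 0.39) did not pass. Neither did Nr1h3 (0.327) and Lpl (0.189) of lipid handling, nor Atf4 (0.0929) and Asns (0.166) of the stress response.

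Not called with IL1b were alternative activation with 2 higher (4 adjusted over the list alone), which had a median of -0.15 and an upward test, inflammatory cytokines with 0 (2 adjusted over the list alone) and the inflammasome list with 0 (1 adjusted over the list alone). DESeq2 called 1 gene each in the cytokine, inflammasome, glycolysis and type I lists and 0 in MHC class II, and edgeR had 3, 2, 4, 5 and 5 genes at an unadjusted p under 0.05. Receptors had a median of -0.04 (-0.01 with bounds) and a mean of 0.07 under a downward test, and cholesterol biosynthesis a median of 0.07 under a downward test. In both, and in MHC class I, hypoxia, TCA cycle, oxidative phosphorylation, cell cycle, checkpoint and lysosome, 0 genes passed edgeR's test (0 adjusted over the list alone), and DESeq2 called 0. At an unadjusted p under 0.05 edgeR had 0 receptor, 0 cholesterol, 0 MHC class I, 7 hypoxia, 2 TCA cycle, 3 oxidative phosphorylation, 1 cell cycle, 5 checkpoint and 3 lysosome genes. Il6 was at least 9.41-fold higher than 0 counts but did not pass (adjusted p = 0.063, but 0.00935 with no filter on low counts and 0.0334 without IL1b library 2). Tnf (0.57 ± 0.21, adjusted p = 0.572), Cd274 (0.32 ± 0.13, adjusted p = 0.755) and Ciita (-0.39 ± 0.13, adjusted p = 0.417) did not pass. Cxcl9 (0.75 ± 0.19, adjusted p = 0.142) and Arg1 (1.11 ± 0.31, adjusted p = 0.244) did not pass in edgeR and did in DESeq2 (0.000172 and 0.00854). Cxcl9 also passed in the model of only the 6 libraries (0.000175) and without the third TNF and LPS libraries (0.0477). Of 12 macrophage identity and 10 granulocyte markers 0 passed in edgeR or DESeq2, and 1 of each list had an unadjusted p under 0.05.

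LPS added to IFNg raised Clec4e (ENSMUSG00000030142, chromosome 6, 123281789 to 123289870), a receptor for mycobacterial glycolipid, which rose from 4.49 to 332 ± 52.2 CPM by 6.21 ± 0.23 (adjusted p = 7.2e-15, n = 3), and Clec4n (ENSMUSG00000023349, chromosome 6, 123229843 to 123247021) from 1.56 to 147 ± 21.3 CPM by 6.53 ± 0.50. Nos2 rose to 3091 ± 425 CPM by 6.96 ± 0.27 (adjusted p = 5.28e-13). Slc7a11 reached 31.0 ± 10.9 CPM against 1 count, a ratio of 1620 (95% counting interval 290 to 63900). Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), a peroxidase of granulocytes, fell from 10.4 ± 2.70 to 0.246 CPM (adjusted p = 0.000139).

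Oxidative stress genes counted 19 higher and 1 lower of 24 (19 and 1 adjusted over the list alone; median 1.72, camera adjusted p = 2.76e-44), with Hmox1 up by 3.87 ± 0.16 and Prdx1 by 3.76 ± 0.12. The nitric oxide and antimicrobial effector list had 12 higher and 3 lower of 25 (14 and 3 adjusted over the list alone; camera adjusted p = 1.58e-15), and Arg1, outside it, rose by 1.76 ± 0.30. NF-kappaB genes counted 21 higher and 3 lower of 35 (24 and 4 adjusted over the list alone; median 0.72, camera adjusted p = 1.88e-13), with Sod2 up by 3.06 ± 0.14 and Cd83, Rel and Nfkb1 lower. Inflammatory cytokines counted 9 higher and 2 lower of 21 (9 and 3 adjusted over the list alone; camera adjusted p = 0.000453). Il1b rose to 65.1 ± 10.6 CPM by 4.88 ± 0.42, Il12b was at least 42.8-fold and Il6 at least 40.1-fold higher than 0 counts, and Tnf rose by 1.80 ± 0.21. Chemokines counted 6 higher and 1 lower of 17 (6 and 2 adjusted over the list alone; camera adjusted p = 0.00858, adjusted p = 0.0598 with an estimated correlation). Hypoxia genes counted 18 higher and 3 lower of 34 (21 and 3 adjusted over the list alone; median 0.99, camera adjusted p = 9.13e-07), with Vegfa up by 1.82 ± 0.22. Glycolysis counted 11 higher and 1 lower of 19 (11 and 1 adjusted over the list alone; camera adjusted p = 9.59e-09), with Slc2a1 up by 1.89 ± 0.14.

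The IFNg response list had 13 higher and 3 lower of 29 (14 and 3 adjusted over the list alone; median 0.31, camera adjusted p = 0.000175), with Cxcl9 up by 1.69 ± 0.19, Cxcl10 by 1.27 ± 0.21 and Gbp2b, Gbp8 and Gbp9 lower. Type I interferon genes counted 18 higher and 1 lower of 36 (23 and 2 adjusted over the list alone; camera adjusted p = 9.59e-09), with Ifit1 up by 0.94 ± 0.14. In MHC class II 7 of 12 fell and 0 rose (7 adjusted over the list alone; median -0.53, camera adjusted p = 0.000189, adjusted p = 0.0862 with an estimated correlation). Ciita fell to 318 CPM by 1.24 on the log2 scale (adjusted p = 7.36e-08) and H2-Ab1 was at -0.52 ± 0.14. Checkpoint genes counted 8 higher and 4 lower of 21 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.0852 with an estimated correlation, and 0.0507 without IFNg library 1). Cd274 rose to 882 CPM by 1.57 ± 0.13. The inflammasome list had 8 higher and 1 lower of 34 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0308) or 7 and 2 with RPKM totals, and lipid handling 11 and 4 of 24 (12 and 4 adjusted over the list alone; camera adjusted p = 0.00265, adjusted p = 0.0781 with an estimated correlation).

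Cell cycle genes fell, 28 lower and 0 higher of 34 (30 adjusted over the list alone; median -1.88, camera adjusted p = 7.43e-30), with Plk1 at -2.85 ± 0.27. Granulocyte precursor markers fell with them, 8 lower and 0 higher of 10, with S100a9 at 15.9 CPM and Elane at 0 counts. Both B cell markers fell (Ighm at 81.4 CPM), Klrk1 of the NK list fell to 32.2 CPM, and of the T cell list 1 gene rose. Macrophage identity markers counted 3 higher and 2 lower of 12, or 2 and 3 with RPKM totals. Lists not called were alternative activation with 6 higher and 12 lower (6 and 13 adjusted over the list alone), the lysosome with 9 and 3 (9 and 6), the stress response with 6 and 9 (6 and 9), receptors with 8 and 6 (8 and 8), MHC class I with 3 and 2 (3 and 2), and oxidative phosphorylation with 0 and 0 (0 and 0; median -0.04). In the last, 5 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 0. The TCA cycle had 2 higher and 4 lower (2 and 6 adjusted over the list alone), with a median of 0.06 and a mean of -0.08 under a downward test, and cholesterol biosynthesis 4 and 2 (4 and 3), with a median of -0.03 and a mean of 0.04 under an upward test. With RPKM totals the TCA median was -0.02 (2 higher and 7 lower) and the receptor median -0.04 (6 and 8), while the lysosome had 6 and 6 and oxidative phosphorylation 0 and 2. In all 2348 genes changed (1184 higher and 1164 lower, or 20.3%), 992 of them at least 2-fold, and 2403 with RPKM totals, 962 higher and 1441 lower. The third TNF and LPS libraries had the fewest genes with a count (10820 and 11041). Without both, which was chosen after seeing the data, 2312 genes changed with LPS and 4938 with TNF. The first LPS library had r = 0.423 with the mean TNF profile and 0.351 with its own group, both across genes, and without it 2158 genes changed.

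Hypoxia added to IFNg raised genes of the hypoxia response and of glycolysis and lowered genes of the cell cycle. Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), an oxygen-sensing prolyl hydroxylase, rose from 0.743 ± 0.580 to 129 ± 9.69 CPM by 7.47 ± 0.76 (adjusted p = 2.36e-06, n = 3). Vldlr (ENSMUSG00000024924, chromosome 19, 27216484 to 27254231), a lipoprotein receptor, was at least 389-fold higher than 0 counts (adjusted p = 0.00201). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) rose from 4.23 ± 0.440 to 414 ± 26.6 CPM by 6.61 ± 0.33 (adjusted p = 1.07e-10). mt-Nd6 (ENSMUSG00000064368, mitochondrial genome, 13552 to 14070) fell from 299.7 ± 59.2 to 21.6 ± 0.931 CPM (adjusted p = 2.1e-08).

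Of 34 hypoxia response genes 27 rose and 0 fell (27 and 2 adjusted over the list alone; median 2.44, camera adjusted p = 2.3e-51), with Adm at least 222-fold and Ak4 at least 172-fold higher and Vegfa up by 2.24 ± 0.22. Of 19 glycolysis genes 13 rose and 0 fell (15 adjusted over the list alone; median 2, camera adjusted p = 4.22e-39), with Hk2, which phosphorylates glucose, up by 3.20 ± 0.13 and Slc2a1 at 811 ± 37.5 CPM, up by 3.51 ± 0.15. In the TCA cycle 13 of 24 fell and 0 rose (13 adjusted over the list alone; median -0.33, camera adjusted p = 0.000126), with Idh3a at -1.63 ± 0.22. In oxidative phosphorylation 9 of 51 fell and 0 rose (6 adjusted over the list alone; median -0.24, camera adjusted p = 0.0032, adjusted p = 0.431 with an estimated correlation), and 27 fell with RPKM totals. Of 34 cell cycle genes 30 fell and 0 rose (31 adjusted over the list alone; median -2.51, camera adjusted p = 3.19e-40), with Rrm2, a subunit of ribonucleotide reductase, at -4.41 ± 0.37. Of 10 granulocyte precursor markers 0 passed edgeR's test here, 3 had an unadjusted p under 0.05, DESeq2 called 1, and 2 fell with RPKM totals. Stress response genes counted 16 higher and 2 lower of 25 (18 and 3 adjusted over the list alone; median 0.61, camera adjusted p = 0.000113).

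Nos2 rose to 1155 ± 165 CPM by 5.54 ± 0.25, and the nitric oxide and antimicrobial effector list counted 9 higher and 1 lower of 25 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000375), or 6 and 2 with RPKM totals. NF-kappaB genes counted 13 higher and 1 lower of 35 (16 and 2 adjusted over the list alone; camera adjusted p = 8.79e-05, adjusted p = 0.0918 with an estimated correlation), with Ier3 up by 4.83 ± 0.41, and 10 and 3 with RPKM totals. Tnf fell from 26.4 to 14.8 CPM (-0.84 ± 0.22, adjusted p = 0.00511). The IFNg response list had 17 higher and 1 lower of 29 (18 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 2.15e-06), but 9 and 2 with RPKM totals. The tryptophan-degrading enzyme gene Ido1 rose from 2.16 to 78.9 ± 15.5 CPM and Cxcl9 by 1.53 ± 0.19, while Serpina3g fell. Ciita (0.07 ± 0.13, adjusted p = 0.779) did not pass and was at -0.178 with RPKM totals. MHC class II had 7 higher and 0 lower of 12 (8 adjusted over the list alone; median 0.55, camera adjusted p = 0.000965, adjusted p = 0.178 with an estimated correlation), with H2-Ab1 up by 0.83 ± 0.14. MHC class I had 8 higher and 1 lower of 22 (12 and 1 adjusted over the list alone; camera adjusted p = 0.0419, adjusted p = 0.329 with an estimated correlation). This call was lost with RPKM totals (0.256, with 1 higher and 2 lower) and without hypoxia library 1 (0.0695) or 2 (0.0736) or IFNg library 2 (0.0937). Checkpoint genes counted 8 higher and 3 lower of 21 (9 and 3 adjusted over the list alone; camera adjusted p = 0.000868), with Cd274 up by 1.33 ± 0.13.

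Receptors of the stimuli had 10 higher and 3 lower of 32 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0321, adjusted p = 0.329 with an estimated correlation), a call lost with RPKM totals (0.122, with 4 and 4) and without IFNg library 1 (0.0742). Il1r2, the decoy receptor for IL1, rose from 1.47 ± 0.645 to 55.2 ± 8.15 CPM. Lists not called were the type I response with 2 higher and 5 lower (2 and 5 adjusted over the list alone), but 0 and 19 with RPKM totals, cytokines with 5 and 1 (5 and 1), chemokines with 3 and 4 (3 and 5), lipid handling with 5 and 5 (5 and 5) and the inflammasome list with 4 and 6 (4 and 6). Also not called were cholesterol biosynthesis with 5 and 2 (6 and 3; median 0.20), alternative activation with 8 and 3 (8 and 4; median 0.17), the lysosome with 8 and 2 (9 and 2; median 0.07) and oxidative stress with 6 and 4 (6 and 4; median 0.02). With RPKM totals these last 4 medians were -0.05, -0.08, -0.17 and -0.23, with 3 and 4, 5 and 6, 6 and 10, and 5 and 8 genes higher and lower. Cytokines then had 4 and 2, lipid handling 3 and 9 and the inflammasome list 1 and 9. Ifit1 (-0.26 ± 0.14, adjusted p = 0.196) did not pass, but did with RPKM totals (-0.505, adjusted p = 0.00823). Macrophage identity markers counted 5 higher and 1 lower of 12 (4 and 3 with RPKM totals), the B cell list 1 and 1 (0 and 1 with RPKM totals, Ighm at 247 CPM), and the T cell list 1 higher. In all 2918 genes changed (1556 higher and 1362 lower, or 25.2%), 1174 of them at least 2-fold. With RPKM totals 3452 changed, 888 higher and 2564 lower.

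**Figure D4:**
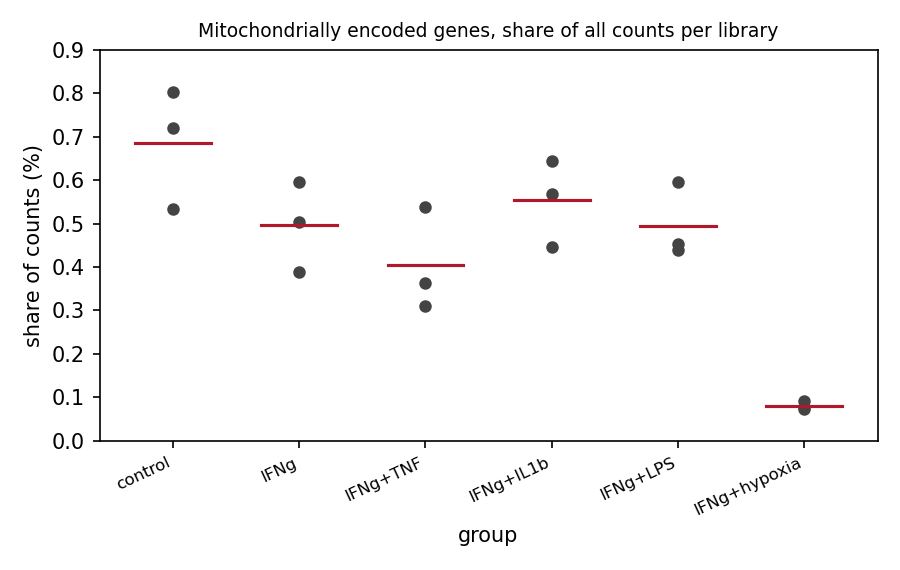
Share of each library's counts (percent) in mitochondrially encoded protein genes, with dots for the 3 libraries of a group and a red line at their mean. The mean was 0.08% with hypoxia and 0.496% with IFNg.

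LPS against TNF, both with IFNg, compared a bacterial and a host signal. Malt1 (ENSMUSG00000032688, chromosome 18, 65430938 to 65479067), a paracaspase of NF-kappaB signalling, was lower with LPS, at 31.9 ± 3.32 against 230.6 ± 14.1 CPM (-2.85 ± 0.15, adjusted p = 1.53e-13, n = 3). Il1b was lower, at 65.1 against 1688 CPM (-4.70 ± 0.36), as were Ptgs2 at 469 against 5847 CPM (-3.64 ± 0.16) and Cd14 at -3.03 ± 0.14. Ighm was higher with LPS (3.13 ± 0.18, adjusted p = 5.63e-12). Gbp2b was higher too, at 557 against 111 CPM.

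Of 35 NF-kappaB genes 29 were lower with LPS and 0 higher (30 and 1 adjusted over the list alone; median -1.39, camera adjusted p = 8.08e-33). Cytokines counted 11 lower and 2 higher of 21 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0007), the hypoxia list 23 and 1 of 34 (26 and 2 adjusted over the list alone; median -1.83, camera adjusted p = 3.91e-22) and oxidative stress 16 and 0 of 24 (17 and 0 adjusted over the list alone; camera adjusted p = 4.18e-13). Glycolysis counted 9 lower and 1 higher of 19 (10 and 1 adjusted over the list alone; camera adjusted p = 1.77e-08), with Slc2a1 at -2.11 ± 0.14, and nitric oxide and antimicrobial effectors 13 and 4 of 25 (13 and 4 adjusted over the list alone; camera adjusted p = 5.9e-06), with Nos2 at -2.70 ± 0.22. With RPKM totals the latter counted 9 lower and 5 higher. The IFNg response list had 13 lower and 3 higher of 29 (15 and 3 adjusted over the list alone; camera adjusted p = 0.000388), 7 and 5 with RPKM totals, with Cxcl9 at -1.46 ± 0.19. Type I genes counted 11 lower and 0 higher of 36 (14 adjusted over the list alone; camera adjusted p = 0.00441, adjusted p = 0.176 with an estimated correlation), but 5 and 3 with RPKM totals, where the call was lost (0.0752). MHC class I genes counted 6 lower and 2 higher of 22 (6 and 2 adjusted over the list alone; median -0.21, camera adjusted p = 0.015, adjusted p = 0.184 with an estimated correlation). That median was 0.03 with RPKM totals, where 5 were lower and 3 higher and the call was lost (0.139), as it was without the third TNF and LPS libraries (0.104). Checkpoint genes counted 11 lower and 4 higher of 21 (11 and 4 adjusted over the list alone; camera adjusted p = 0.006, adjusted p = 0.0609 with an estimated correlation), and receptors 11 and 4 of 32 (12 and 4 adjusted over the list alone; camera adjusted p = 0.00027, adjusted p = 0.0643 with an estimated correlation). With RPKM totals these counted 7 and 5, and 10 and 7.

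Cell cycle genes were higher with LPS than with TNF, 26 higher and 0 lower of 34 (26 adjusted over the list alone; median 1.39, camera adjusted p = 4.12e-15), and so were 4 of 10 granulocyte markers and 0 were lower. Alternative activation genes counted 10 higher and 2 lower of 28 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000406), with Mrc1 at 2.99 ± 0.40, and the TCA cycle 11 and 1 of 24 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000406), or 19 and 1 with RPKM totals. Oxidative phosphorylation had 13 higher and 0 lower of 51 (13 adjusted over the list alone; camera adjusted p = 0.00171, adjusted p = 0.376 with an estimated correlation, and 0.056 without TNF library 2), and 31 were higher with RPKM totals. The lysosome had 9 higher and 2 lower of 30 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0484, adjusted p = 0.514 with an estimated correlation). With RPKM totals 21 were higher and 1 lower. The call was lost with DESeq2's size factors (0.0578) and without TNF library 1 (0.25), LPS library 2 (0.0899) or LPS library 3 (0.107). Not called were MHC class II with 2 higher and 4 lower (2 and 4 adjusted over the list alone), the inflammasome list with 2 and 7 (2 and 7) and cholesterol biosynthesis with 1 and 3 (1 and 3). Chemokines had 5 and 4 (5 and 4), with a median of 0.16, or 0.00 with genes near 0 counts set to no change, and a mean of -0.28 under a downward test. Lipid handling had 6 and 7 (7 and 8), with a median of -0.12 and a mean of 0.17 under an upward test, and the stress response 10 and 7 (10 and 8), with a median of 0.10 and a mean of -0.09 under an upward test. With RPKM totals the inflammasome median was 0.07 (8 higher and 4 lower) and the lipid handling median 0.12 (8 and 4), while MHC class II had 4 and 3, cholesterol biosynthesis 3 and 1 and the stress response 11 and 3. Arg1 (-0.05 ± 0.27, adjusted p = 0.926) did not pass. In all 2926 genes changed (1407 higher with LPS and 1519 lower, or 25.3%), 1224 of them at least 2-fold. With RPKM totals 3505 changed, 2621 higher and 884 lower.

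TNF against IL1b, both with IFNg, compared the additions of 2 inflammatory cytokines. Slc7a11 had 303 ± 37.1 CPM with TNF and 2 counts with IL1b, a ratio of 7070 (95% counting interval 1960 to 58400). Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), a neutrophil-attracting chemokine, had 1 count with IL1b, a ratio of 724 (130 to 28600). Nos2 was higher with TNF, at 20100 against 198 CPM (6.67 ± 0.26, adjusted p = 1.12e-13, n = 3), as was Hmox1 (4.39 ± 0.16, adjusted p = 1.77e-17), and Trem1, an amplifying receptor, was at least 406-fold higher. Lower with TNF were Ciita (-1.54 ± 0.13), Gbp2b (-3.73 ± 0.17) and Mrc1 (-5.31 ± 0.39).

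NF-kappaB genes counted 29 higher with TNF and 1 lower of 35 (29 and 1 adjusted over the list alone; median 2.09, camera adjusted p = 2.29e-27), oxidative stress 21 and 1 of 24 (22 and 2 adjusted over the list alone; camera adjusted p = 2.52e-28) and the hypoxia list 28 and 3 of 34 (29 and 3 adjusted over the list alone; median 2.72, camera adjusted p = 6.7e-18). Nitric oxide and antimicrobial effectors counted 15 and 5 of 25 (16 and 5 adjusted over the list alone; camera adjusted p = 4.55e-09), glycolysis 12 and 2 of 19 (12 and 2 adjusted over the list alone; camera adjusted p = 7.68e-10) and cytokines 15 and 2 of 21 (15 and 3 adjusted over the list alone; camera adjusted p = 0.000419). The IFNg response list had 18 and 3 of 29 (18 and 4 adjusted over the list alone; camera adjusted p = 5.9e-05), the type I list 22 and 2 of 36 (22 and 2 adjusted over the list alone; camera adjusted p = 1.94e-05) and the checkpoint list 11 and 3 of 21 (11 and 3 adjusted over the list alone; camera adjusted p = 0.00325). The inflammasome list had 12 and 4 of 34 (12 and 4 adjusted over the list alone; median 0.17, camera adjusted p = 0.0368) and receptors 15 and 7 of 32 (15 and 7 adjusted over the list alone; median 0.30, camera adjusted p = 0.00333, adjusted p = 0.133 with an estimated correlation). With RPKM totals these medians were -0.16 (8 and 7) and -0.02 (12 and 9), and the inflammasome call was lost (0.0842). Cytokines then counted 14 and 4, the IFNg response 13 and 6, the type I list 13 and 4 and the checkpoint list 10 and 6.

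Cell cycle genes were lower with TNF, 31 lower and 0 higher of 34 (32 adjusted over the list alone; median -3, camera adjusted p = 4.8e-28), beside 7 of 10 granulocyte markers lower and 0 higher. The TCA cycle counted 13 lower and 1 higher of 24 (13 and 1 adjusted over the list alone; camera adjusted p = 0.00325), alternative activation 13 and 7 of 28 (13 and 8 adjusted over the list alone; camera adjusted p = 0.0011) and oxidative phosphorylation 21 and 0 of 51 (21 adjusted over the list alone; camera adjusted p = 0.00423, adjusted p = 0.407 with an estimated correlation). With RPKM totals the TCA cycle had 21 lower and 1 higher and oxidative phosphorylation 36 lower. Not called were MHC class I with 11 higher and 2 lower (11 and 2 adjusted over the list alone), lipid handling with 12 and 7 (13 and 7) and the lysosome with 6 and 10 (7 and 10). MHC class II had 2 and 3 (2 and 3), with a median of -0.02 and a mean of 0.16 under a downward test. Chemokines had 5 and 5 (5 and 6), with a median of -0.23 (0.00 with bounds) and a mean of 0.64 under an upward test. Cholesterol biosynthesis had 3 and 4 (3 and 3), with a median of -0.17 under an upward test, and the stress response 7 and 11 (7 and 11), with a median of -0.47 and a mean of 0.54 under a downward test. With RPKM totals MHC class I had 5 higher and 7 lower, the lysosome 2 and 18, MHC class II 0 and 5, chemokines 4 and 7 and cholesterol biosynthesis 3 and 9. Arg1 (0.70 ± 0.28, adjusted p = 0.0562) did not pass, but did in DESeq2 (0.0185) and with DESeq2's size factors (0.0461). It also passed without TNF library 2 (0.0243) or 3 (0.0474), without IL1b library 2 (0.027) and without the third TNF and LPS libraries (0.0216). In all 4860 genes changed (2418 higher with TNF and 2442 lower, or 42%), 2565 of them at least 2-fold. With RPKM totals 5459 changed, 1521 higher and 3938 lower.

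Overlaps asked whether the additions changed shared genes. TNF and LPS shared 1110 higher and 1031 lower genes, with 16 opposite, where independent lists of those sizes would share 262.1, 263.1 and 525.4. TNF and hypoxia shared 895 higher and 804 lower with 358 opposite (344.5, 307.9 and 653.3 for independent lists), and LPS and hypoxia 451 and 432 with 272 opposite (159.3, 137.1 and 296.1). With RPKM totals the shared higher and lower genes were 845 and 1347 for TNF and LPS, 489 and 1652 for TNF and hypoxia, and 277 and 688 for LPS and hypoxia. IL1b shared 31 of its 31 higher genes with LPS and 30 with TNF, where independent lists would share 3.2 and 6.9, and 15 with hypoxia (4.2). Opposite calls of IL1b numbered 1 with LPS, 3 with TNF and 9 with hypoxia (3.5, 7.9 and 4.2 for independent lists). Simulated unchanged groups against the same IFNg libraries shared at most 1 call. Such groups have almost no calls, so this is the value with no effect and does not measure what the shared libraries add to the overlaps. The covariance of log2 fold changes was 1.639 for TNF and LPS, 1.107 for TNF and hypoxia and 0.649 for LPS and hypoxia, where the simulated mean was 0.153 for each. With IL1b it was 0.496 for TNF (0.151 simulated), 0.45 for LPS (0.152) and 0.289 for hypoxia (0.152). The correlation across genes, which are not independent replicates, was above its simulated mean for TNF and LPS (r = 0.761 against 0.498) and for IL1b and LPS (0.516 against 0.497). It was below it for TNF and hypoxia (0.475 against 0.491), LPS and hypoxia (0.422 against 0.496), TNF and IL1b (0.375 against 0.491) and IL1b and hypoxia (0.307 against 0.491). Unchanged groups reach such a correlation through the shared IFNg libraries alone. Effects of an addition add variance of their own, which can lower the correlation. A value above or below the simulated mean therefore does not measure how far 2 additions share effects.

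Of 744 genes that IFNg raised at least 2-fold over control, TNF raised 261 and lowered 219, LPS raised 177 and lowered 124, hypoxia raised 233 and lowered 72, and IL1b raised 12 and lowered 1. Another 744 genes, matched on level, had passed the test for IFNg against control in neither direction. Their counts were 146 and 196 for TNF, 61 and 89 for LPS, 89 and 99 for hypoxia, and 0 and 0 for IL1b. In the draws with simulated unchanged groups, IFNg raised 887.1 genes at least 2-fold on average, and the additions gave at most 0 higher and 1 lower. Such groups have almost no calls, so this does not measure what the shared libraries add to these counts. The covariance with the IFNg effect was -0.248 for TNF, -0.241 for IL1b, -0.231 for LPS and -0.09 for hypoxia, where the simulated mean was -0.153, -0.157, -0.151 and -0.151. With RPKM totals TNF raised 165 and lowered 242 of the genes IFNg raised, and hypoxia raised 134 and lowered 95.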

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

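Scaling to RPKM totals and leaving out the third TNF and LPS libraries were tests chosen after the results were seen. With DESeq2's size factors, no filter on low counts, the RPKM totals or without those 2 libraries, all 7 counts of changed genes stayed within 1.5 times their value. Of the 94 gene list calls, 93 held with DESeq2's size factors, 93 with no filter, 89 with RPKM totals and 93 without those 2 libraries. RPKM totals called 1 more, the chemokines with TNF (0.0266). Over the fits that left out 1 library, 548 of 564 held and 16 were lost. Fry tests whether a list's genes move on balance one way, not whether they differ from other genes as camera does, so its calls do not bear on that difference. It called 93 of the 94, not 1 (glycolysis with IL1b, 0.0897), and 3 more, the chemokines with TNF (5.96e-06), LPS against TNF (0.0272) and TNF against IL1b (0.000319). With no filter the stress response with IL1b was lost (0.0555), and the cause was not tested. Named genes kept direction and call in 401 cases with DESeq2's size factors, 398 with no filter, 390 with DESeq2, 383 with only the 6 libraries, 392 with RPKM totals and 394 without those 2 libraries. The number of such cases (a gene in a comparison) differed between settings. With DESeq2, 6 of them lost the call and 3 gained it. With only the 6 libraries 1 lost it and 2 gained it, and with RPKM totals 5 lost it, 1 gained it and 4 reversed. Of the fits that left out 1 library, 2286 kept it, 115 lost it, 4 gained it and 7 reversed.

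The 2-fold threshold lowered every count by its construction. IFNg against control then had 1292 genes, TNF 2843, IL1b 15, LPS 992, hypoxia 1174, LPS against TNF 1224, and TNF against IL1b 2565. TNF and LPS then shared 466 higher and 454 lower genes, TNF and hypoxia 335 and 359, and LPS and hypoxia 150 and 208. Of the genes IFNg raised, TNF then raised 170 and lowered 145, LPS 97 and 58, and hypoxia 92 and 33. For IL1b, DESeq2 called 86 genes and the model of only 6 libraries 68, and the cause was not tested.

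With RPKM totals TNF and hypoxia shared 489 higher and 1652 lower genes and LPS and hypoxia 277 and 688. TNF then raised 165 and hypoxia 134 of the genes IFNg raised. By its construction this scaling moves every fold change of a comparison by about its median shift. Values close to 0 changed sign: Il1b for IFNg against control (-0.128), H2-Ab1 (-0.079) with TNF, Ciita (-0.178) with hypoxia, and Arg1 for LPS against TNF (0.189). Of these 0 had been called. Without the 2 libraries named above, Arg1 for LPS against TNF was 0.058.

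Leaving out 1 library in turn gave 2228 to 2413 genes for IFNg against control, 4538 to 4872 for TNF, 15 to 35 for IL1b, 1860 to 2198 for LPS, 2252 to 2449 for hypoxia, 2413 to 2734 for LPS against TNF and 4223 to 4597 for TNF against IL1b. The lowest values for IL1b came without IFNg library 1 or IL1b library 3. Genes that had not passed the test and changed sign were Il1b for IFNg against control, at -0.263 to 0.833 (without control library 1 -0.262 and 3 -0.263, without IFNg library 2 -0.127 and 3 -0.131), and Arg1 for LPS against TNF, at -0.237 to 0.329 (without TNF library 1 0.329 and LPS library 3 0.177). The other was Il1b with IL1b, at -0.321 to 0.568 (without IL1b library 2 -0.321). The cause was not tested.

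With the replicate number as a block, 2917 genes changed for IFNg against control, 5340 for TNF, 48 for IL1b, 2515 for LPS, 3112 for hypoxia, 3112 for LPS against TNF and 5004 for TNF against IL1b. All 94 list calls held under the block. Of the named genes 396 cases held, 5 lost the call (Arg2 and Cox5a with hypoxia, Asns with IL1b, Ccl24 with TNF and Stc2 with LPS) and 1 gained it (Arg1 for TNF against IL1b, 0.0425). Deviations from the group means correlated at -0.095 to 0.233 between same-numbered libraries and at -0.193 to 0.175 between others, and 9 of 45 same-numbered pairs were over 0.1, so the numbers were not taken as pairing the samples. Of 18 libraries 12 correlated best with their own number, a hint from the data and not from the design.

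Depth and spread limit the low genes. The median biological coefficient of variation was 1.12 among 1036 genes under 1 CPM and 0.12 among 3017 genes above 64 CPM. On simulated counts the test recovered 19.4% of genes changed 1.5-fold for IL1b and 59.7% of those changed 2-fold.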

Other observations

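The tests of granulocyte precursors, of scaling, of 1 library as a source, of the position of libraries between group means and of exchanged labels were chosen after the results were seen. Some receptors for the added signals passed edgeR's test. Il1r1, which transmits the IL1 signal, had 0 counts in the 3 IFNg libraries and 124 with TNF, where it stood at 2.9 ± 1.82 CPM (SD, n = 3, adjusted p = 0.00371). It had 26 counts in control (adjusted p = 0.0604) and 4 with IL1b (adjusted p = 1), and neither passed against IFNg. The decoy receptor Il1r2 stood at 1.47 ± 0.645 CPM with IFNg and 55.2 ± 8.15 with hypoxia (adjusted p = 5.99e-05). Il1rap, the shared co-receptor, stood at 10.9 CPM in control and 7.17 with IFNg and did not pass (adjusted p = 0.313). Tnfrsf1a rose from 186 CPM in control to 436 with IFNg (adjusted p = 1.57e-08) and 638 with TNF (adjusted p = 0.000749 against IFNg). Tnfrsf1b fell from 456 to 212 with IFNg (adjusted p = 2.29e-05) and stood at 837 with TNF (adjusted p = 1.9e-09). Tlr4 fell from 314 ± 25.3 CPM with IFNg to 178 ± 17.8 with TNF (adjusted p = 8.19e-05). Hif1a, the oxygen-regulated transcription factor, rose from 328 ± 21.1 CPM with IFNg to 1670 ± 186 with TNF (adjusted p = 3.01e-15) and did not pass with hypoxia, at 366 CPM (adjusted p = 0.338).

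Of 9 measured dendritic cell markers 5 rose with IFNg: Xcr1, Clec9a (0.244 to 83.9 CPM), Dpp4, Itgae (0 to 0.589 CPM) and Bst1 (17.7 to 307 CPM). Flt3 (1.78 to 1.86 CPM), Zbtb46 (0 to 0.296), Siglech (1.35 to 0.765) and Ccr7 (1.94 to 1.14) did not pass. TNF raised 2 (Ccr7, 1.14 to 37.5 CPM, and Bst1) and lowered 2 (Clec9a and Dpp4), LPS raised 2 and lowered 1 (2 and 2 with RPKM totals), and hypoxia raised 2 (Dpp4, 11.8 to 86.6 CPM, and Bst1). LPS against TNF and TNF against IL1b each had 2 higher and 2 lower. The fibroblast list had 1 higher of 5 with IFNg (Dcn). The endothelial list of 3 had Pecam1 higher with IFNg (0.547 to 24.1 CPM), 1 higher and 1 lower with TNF and with LPS, and Kdr lower with hypoxia (19.2 to 7.27 CPM). Of the 2 megakaryocyte markers Pf4 rose with hypoxia (25.5 to 58.5 CPM). The mast cell and basophil list had 1 measured gene, with 0 calls by edgeR or DESeq2 and an unadjusted p under 0.05 in 2 of the 7 comparisons, and of erythroid markers 0 were measured.

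Mitochondrially encoded genes fell with hypoxia, 7 of 10 tested (7 adjusted over the list alone) with a median of -2.91: mt-Nd1, mt-Nd2, mt-Co1, mt-Nd4, mt-Nd5, mt-Nd6 and mt-Cytb. They held 0.08% ± 0.009 of counts (SD, n = 3), against 0.496% ± 0.104 with IFNg, 0.685% ± 0.138 in control, 0.404% ± 0.119 with TNF, 0.554% ± 0.1 with IL1b and 0.495% ± 0.087 with LPS. With RPKM totals the median was -3.16, but that scaling moves every fold change by about the same amount, here -0.245. This move was fixed beforehand, so the value does not test scaling as the source. A bias of short or abundant transcripts is argued against, since 182 nuclear genes matched on length and level had a median of 0.1, with 49 higher and 21 lower. That hypoxia lowers these transcripts is a hypothesis found and tested on the same data.

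Cell cycle genes fell with TNF, LPS and hypoxia, and a smaller share of granulocyte precursors, which divide, may account for part of it. Of the 12 granulocyte markers 1, Camp, was also in a pathway list, and the most abundant, S100a9, stood at 42.8 CPM with IFNg. With TNF the granulocyte median minus the cell cycle median was -1.3 (-4.39 and -3.08, SE 1.06) and with LPS -1.2 (-3.09 and -1.88, SE 1.05). The markers fell no less than the cell cycle genes, so this stays open for both. The comparison uses fold changes and not levels, so it cannot say how much of the fall such cells could account for. With hypoxia the difference was 1.84 (-0.67 and -2.51, SE 0.23), which argues against a loss of the marked cells as a whole there. Mpo (-1.9), Elane (-2.35) and Ctsg (-2.08) did fall nearly as far, without passing edgeR's test. The other markers stood at -0.95 to 0.22, so a loss of part of these cells stays open. Each SE of a difference was taken across genes as if they were independent. It does not measure the spread between libraries. Slower division of the macrophages under each addition stays open and was not tested.

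The NF-kappaB list was lower with LPS than with TNF, with a median of -1.39. Thinning every library to the smallest total left -1.37. Fold changes were already scaled to library size, so thinning could hardly move the median and does not decide on total count. That 1 library was the source is argued against, since the highest median without any 1 library was -1.26. The rule fixed beforehand for a library under the other group's label was any library that correlated better with the other group. It was met by 1 of the 6, LPS library 1 (r = 0.423 with the TNF mean and 0.351 with its own). These were means of 3 libraries against 2. Position between the group means over the tested genes, chosen after the results were seen, argues against such a label. With the own group's mean without the library at 0 and the other's at 1, the 6 lay at 0.11 to 0.301 (SD 0.078). LPS library 1 lay at 0.298, and without it the NF-kappaB median was -1.34. Exchanged labels of both groups cannot be told apart from correct ones, since no gene that answers LPS alone was fixed, and the type I interferon list had a median of -0.26.

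For each comparison, the 6 libraries have 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes. The real count was 2727 for IFNg against control, 5174 for TNF, 35 for IL1b, 2348 for LPS, 2918 for hypoxia and 4860 for TNF against IL1b, with 0 as the highest other count in each. It was 2926 for LPS against TNF, where the highest other was 14. By squared distance over the tested genes, 14 of the 18 libraries lay nearest to the mean of their own group without them. The other 4, IFNg libraries 1, 2 and 3 and IL1b library 1, lay nearest to the mean of the other of these groups, which held 3 libraries against 2.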
